A study of Mus musculus with 5 samples.

How the data were processed

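Single-cell RNA was measured with 10x 3' chemistry in CD11b-sorted cells from mouse hippocampus. Per the labels, animals received focused ultrasound (FUS) with intravenous microbubbles (FUS+MB), microbubbles alone (MB sham), FUS alone (FUS sham) or no treatment (naive). They were killed 24 h or 72 h later. The transducer had a centre frequency of 1.5 MHz, a focal depth of 60 mm and a radius of 30 mm, and 0.2 mL of gadodiamide was given before magnetic resonance imaging. After perfusion with saline, both hippocampi of each brain were combined. There were 5 libraries. Each of 2 pooled libraries held 5 animals of 1 treatment at 24 h. Each of 3 hashed libraries held animals marked with a hashtag antibody each, combined after staining and loaded on 1 channel. Hashed libraries 1 and 2 had 7 tags, and hashed library 3 had 6 tags and no FUS+MB animal at 24 h. This left 20 hashed animals, 2 for FUS+MB at 24 h and 3 for each other condition.

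The deposited expression values were raw UMI counts per gene and cell. Per the submitters' processing notes, Cell Ranger and Seurat were used with GRCm38.p6 (mm10), with no versions given. The deposited hashtag values were centred log ratios on a natural log scale, and the whole counts behind them were recovered with a largest deviation of 2.36e-11 from a whole number. Mitochondrial content was deposited as a percent of a cell's UMIs, and the margin between hashtags was deposited as a score. Deposited cells had 2001 to 14991 UMIs, at least 1002 genes and less than 10% mitochondrial UMIs, and all deposited hashed cells were singlets by the authors' assignment, which was used. All 15661 cells passed the filter chosen before the data were examined, which asked for 500 UMIs, 200 genes and under 15% mitochondrial UMIs. The gene tables listed 31053 genes for pooled and 32285 for hashed libraries, with 29836 symbols in common.

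Cells were clustered in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) on the shared symbols. Counts were scaled and log-transformed, 2000 variable genes and 30 principal components were kept, and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2) at resolution 1, with 0.5 and 2 as alternatives. Clusters were named from fixed marker lists. A cluster took the name of a type other than microglia when its mean marker level exceeded the median of all clusters by 4 on the log2 scale and 3 markers reached 20 CPM (UMIs scaled to a common total). Otherwise it was called microglia-like when its mean microglia marker level reached 8 on the log2 scale. A cluster with markers of several lymphoid types was called lymphoid-like, and a cluster whose 10 leading genes held more markers of another type than of its own stayed unnamed. These thresholds were set after seeing the data. Scrublet, as built into scanpy, marked 6 of 15661 cells (0.0383%), which is too few for a working doublet call. The cells with the highest 5% of its scores were therefore left out as an added alternative.

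Counts of microglia-like cells were summed per hashed animal (88 to 1085 cells and 432750 to 5534980 UMIs). The sums were fitted in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling, the quasi-likelihood F test and 1 fit over all 7 conditions of the 20 animals. Hashed library entered as a block, because animals of a library shared a channel. The fit held 10546 genes, 11 residual degrees of freedom and a common dispersion of 0.0234, and TMM factors ran from 0.772 to 1.09. As a check of the pairing, deviations of animals from their condition means had a median correlation of 0.276 within libraries and -0.133 between libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Contrasts compared FUS+MB with both shams of the same time, FUS+MB with naive, 72 h with 24 h, shams with naive, and FUS shams with MB shams, and an interaction compared the FUS+MB minus sham difference between times. The fit was tested on simulated data with 100 changed genes per size. At 24 h it found 66% of 2-fold and 95% of 4-fold changes with 6 unchanged genes called. At 72 h it found 73% and 92% with 5 unchanged genes called. Each simulated change was the same in every treated animal, so these shares do not hold for changes that differ between animals. Levels of hashed animals are CPM of an animal's microglia-like sum over its total times the TMM factor, with the standard deviation (SD) over animals. Levels of pools are CPM over the total alone. Changes are log2 fold changes with a standard error (SE). The SE is the size of the change over the square root of its F statistic, and does not measure the spread over animals. A value for 1 library compares its treated animal with the mean of its control animals.

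Gene lists were written before the data were examined: disease-associated microglia, homeostatic microglia, cell cycle, interferon response, antigen presentation, inflammatory cytokine and NF-kB, immediate early and heat shock, glycolysis and hypoxia, oxidative phosphorylation, phagocytosis and lysosome, complement, heme and iron, lipid handling, growth factor and tissue repair, alternative activation, ribosomal protein and mitochondrially encoded genes, and markers of 16 cell types. Marker lists with fewer than 3 measured genes in a comparison were not tested. Lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the lists of a comparison. Some lists share genes, as the microglia markers are all homeostatic genes here.

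Named genes followed a rule fixed before the data were examined. For each contrast these were the 10 largest changes in each direction among genes that passed, averaged at least 20 CPM and had the same direction in every library. Rankings of the largest changes follow this rule, so genes outside it can have larger changes. Members of a list that passed could be named as examples. Where no gene passed, the 3 smallest p in each direction were taken. Apoe, Cst7, Spp1, Lgals3, Lpl, Mki67, Top2a, P2ry12, Tmem119, Cx3cr1, Mrc1, Pf4, Cd74, Ifitm3, Il1b and Ccl4 were always reported. Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d, Uty and gene models with no symbol of their own were left out of naming, 43 of them among 1629 eligible genes at 72 h against shams. List members that did not pass and are named beside their list were chosen after their values were seen. Gene positions come from GENCODE vM21 (GRCm38).

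Class shares and the cycling share were compared by two-sided exact permutation within libraries of which animal was the FUS+MB animal, among it, the 2 shams of its time and the naive animal. The 3 libraries at 72 h gave 64 assignments and a smallest p of 0.0156, and the 2 at 24 h gave 16 and 0.0625. Class p values were adjusted over 14 tests and cycling p values over 2. A cycling cell was a microglia-like cell with at least 2 UMIs over 12 mitotic genes after thinning to 2000 UMIs. Intervals of shares are exact (Clopper-Pearson, 95%), and intervals and floors cover counting error only. Border-associated macrophage-like cells were too few per animal for the planned edgeR comparison, which was left out. Pooled libraries had no replicates, so their summed microglia-like counts were compared as CPM ratios without a p, for genes with at least 200 UMIs over both libraries. Intervals were exact, the floor was 3 counts per library, and list medians were ranked among 10000 random lists matched on expression.

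Other settings fixed before the data were examined were median-ratio size factors, no filter on low counts, a DESeq2 1.42.0 Wald test, no library block, each hashed library left out, all cells, stricter cell filters (1000 UMIs, 500 genes, 5% mitochondrial), Scrublet-marked cells left out, an own hashtag assignment (top tag at least 3 times the next and at least 10 counts), only the conditions of a contrast, and sums without dissociation, mitochondrial and ribosomal genes. The own assignment kept 1562, 4359 and 3267 cells of hashed libraries 1, 2 and 3, and differed from the deposited one in 0, 1 and 12 of them. Limma-voom, library size scaling alone, the doublet score alternative and clusters led by cell cycle genes left out were added after seeing the data. So were edgeR on class counts and directions at an unadjusted p. Figures were drawn with matplotlib 3.10.9.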

Results

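The data describe microglia and other CD11b-sorted cells of the mouse hippocampus after FUS+MB, a treatment used to open the blood-brain barrier. They are compared with shams given 1 component and naive animals. The hashed libraries held 10167 cells of 20 animals, with 1796, 4571 and 3800 cells and 9562609, 22943327 and 22361482 UMIs in hashed libraries 1, 2 and 3. An animal had 99 to 1162 cells and 517484 to 11018408 UMIs. The pooled FUS+MB library held 2184 cells and 16399823 UMIs, and the pooled MB library 3310 cells and 14471892 UMIs. Median UMIs per cell were 6873 and 3377 in these pools, and 4570, 4827 and 4535.5 in the hashed libraries.

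Most cells of each library were microglia-like, except in 1 animal. At 72 h after FUS+MB, microglia-like cells made up 92.1%, 97.4% and 24.3% of the cells of the animals in hashed libraries 1, 2 and 3, against a mean of 96.4% in the shams of that time and the naive animals. The remainder in hashed library 3 was mainly monocyte-like cells, marked by Ly6c2 and Chil3 of blood-derived monocytes. They were 633 of 1162 cells (54.5%, 51.6 to 57.4). In hashed library 1 they were 3 of 277 cells (1.08%, 0.224 to 3.13), and in hashed library 2 there were 0 of 579 cells (upper limit 0.635%). The controls averaged 0.0464%. Dendritic-like cells, marked by class II genes and Cd209a, were 19.2% in hashed library 3, 1.08% in hashed library 1 and 0.345% in hashed library 2, against 0.222% in controls.

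No class passed at 72 h in the two-sided exact permutation test (smallest p possible 0.0156). The mean differences were 6.65 points for dendritic-like cells (exact p = 0.0156, adjusted p = 0.219, higher in 3 of 3 libraries), 18.5 points for monocyte-like cells (exact p = 0.0625, adjusted p = 0.219) and -25.2 points for microglia-like cells (exact p = 0.0469, adjusted p = 0.219). Without hashed library 3 these 3 differences were 0.511, 0.542 and -1.50 points, and without hashed library 1 or 2 the dendritic-like difference was 9.56 or 9.88, the monocyte-like difference 27.2 or 27.7 and the microglia-like difference -36.0 or -38.0. Differences for border-associated macrophage-like, neutrophil-like, lymphoid-like and unnamed cells (cluster 7, led by Ear2 and Ace) were -0.309, -0.124, 0.0414 and 0.532 points. Without hashed libraries 1, 2 and 3 they were -0.643, -0.337 and 0.0546 for border-associated macrophage-like, -0.249, -0.0962 and -0.0277 for neutrophil-like, and -0.118, 0.322 and -0.0797 for lymphoid-like cells. The dendritic-like class was found at clustering resolution 1 and at neither 0.5 nor 2, and at 2 the cluster led by the same class II genes stayed unnamed. The monocyte-like difference was 25.7 points at 0.5 (exact p = 0.0156, adjusted p = 0.125) and 18.8 points at 2 (exact p = 0.0156, adjusted p = 0.156), higher in 3 of 3 libraries. These are not the same class of cells, as the monocyte-like class held 1059 cells at 0.5, against 713 monocyte-like and 298 dendritic-like cells at 1. An edgeR test of class counts per animal called dendritic-like (log2 4.50, adjusted p = 0.000487) and monocyte-like cells (log2 8.11, adjusted p = 2.39e-06) at 72 h. The FUS+MB animals behind these calls were uneven, from 0.345 to 19.2% dendritic-like and from 0 to 54.5% monocyte-like cells, both highest in hashed library 3. The highest control values were 0.767% and 0.220%.

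At 24 h the FUS+MB animal of hashed library 1 held 7 monocyte-like cells among 303 (2.31%, 0.934 to 4.70), and that of hashed library 2 held 0 of 710 (upper limit 0.518%). The shams of that time and the naive animals of both libraries held none at clustering resolution 1. At resolution 0.5 these controls averaged 0.653% monocyte-like cells, and the difference was 1.49 points (exact p = 0.25). At resolution 2 they averaged 0.606% with a highest value of 3.03%, and the difference was 0.714 points (exact p = 0.75). Border-associated macrophage-like cells, the Mrc1- and Pf4-bearing macrophages of brain borders, averaged 0.306% after FUS+MB and 1.29% in controls. Their difference of -0.980 points, lower in 2 of 2 libraries, had the smallest p the design allows (exact p = 0.0625, adjusted p = 0.219). Differences for monocyte-like, dendritic-like, microglia-like, neutrophil-like, lymphoid-like and unnamed cells were 1.16, 0.843, 0.102, -1.07, 0.444 and -0.441 points, and none passed. No class could pass at 24 h, where the smallest p possible was 0.0625. Leaving out hashed library 1 gave 0 and -0.0394 points for monocyte-like and dendritic-like cells, and leaving out hashed library 2 gave 2.31 and 1.72. For neutrophil-like and unnamed cells these were -0.104 and 0 without hashed library 1, and -2.03 and -0.882 without hashed library 2. The border-associated macrophage-like difference was -0.414 without hashed library 1 and -1.55 without hashed library 2. In edgeR on class counts, the border-associated macrophage-like (log2 -2.08, adjusted p = 0.0448) and monocyte-like classes (log2 8.36, adjusted p = 1.13e-05) passed at 24 h. The border-associated macrophage-like call rests on 1 and 2 such cells in the FUS+MB animals of hashed libraries 1 and 2. Each control of those libraries held 2 to 9. The monocyte-like call, made at resolution 1, rests on the 7 cells of the animal of hashed library 1 against counts of 0 in the controls of hashed libraries 1 and 2. The exact permutation test gave p = 0.25 for that class.

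**Figure D1:**
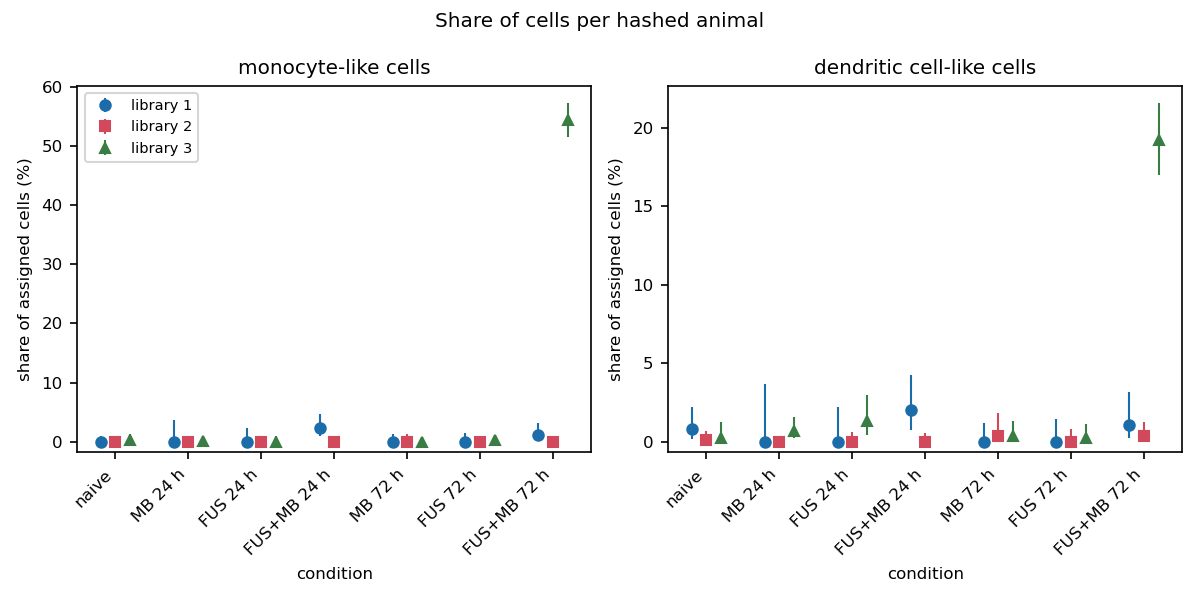
Share of each hashed animal's cells (%, vertical axis) that were monocyte-like (left) and dendritic-like (right) by condition, with 1 point per animal coloured by hashed library and exact 95% intervals. The FUS+MB animal of hashed library 3 at 72 h holds 54.5% monocyte-like and 19.2% dendritic-like cells.

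The comparison of FUS+MB with shams at 72 h asks how microglia-like cells stand 3 days after FUS+MB. Opening of the barrier was not measured here. Spp1, a secreted phosphoprotein of activated microglia, was 117 ± 170 CPM in shams (SD, n = 6) and 4300, 8.60 and 16360 CPM in the FUS+MB animals of hashed libraries 1, 2 and 3, a log2 change of 5.90 (SE 0.60). Cxcl10, an interferon-induced chemokine, rose by 5.65 (SE 0.49), from 13.3 ± 18.0 CPM (SD, n = 6) to 829, 1.03 and 811 CPM. Fn1, which encodes fibronectin, rose by 5.34 (SE 0.36), from 4.08 ± 3.45 CPM (SD, n = 6) to 315, 1.38 and 229 CPM. P2ry12, the purinergic receptor of resting microglia, fell from 3017 ± 397 CPM (SD, n = 6) to 866, 3455 and 611 CPM, a log2 change of -1.08 (SE 0.29). The size of these changes rests on the animals of hashed libraries 1 and 3, and controls of hashed library 2 were also lower in Spp1 (0 to 2.86 CPM) than those of hashed libraries 1 and 3 (23.1 to 504 CPM). Microglia-like cells of these FUS+MB animals lay mostly in clusters 3 and 11 (55.3% and 32.2% in hashed library 1, 44.7% and 45.4% in hashed library 3), against 0.685 to 3.92% in cluster 3 and at most 0.619% in cluster 11 for their shams, so the changes compare cells of almost separate clusters. The mean microglia marker level of cluster 11 was 8.50 on the log2 scale, near the naming threshold of 8, and that of cluster 3 was 10.1.

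In edgeR, 2809 of 10546 genes passed, 1955 higher and 854 lower (69.6% higher), and 4133 had an unadjusted p under 0.05. DESeq2 called 2540 and limma-voom 2376, of which 2323 also passed in edgeR, all in the same direction. The median change of the higher genes was 1.05, 0.12 and 1.22 in hashed libraries 1, 2 and 3, and that of the lower genes was -0.79, -0.11 and -0.98. Without hashed library 1 the count was 7, without hashed library 2 it was 4990, and without hashed library 3 it was 9. The fit without the library block gave 1799, the fit of only these conditions 1034, and the fit without the cycling-led clusters 10, where the FUS+MB animals of hashed libraries 1 and 3 keep 32 and 28 microglia-like cells. With library size scaling alone 3579 genes passed, 34.6% of them higher, and the median of all genes shifted to -0.25 from -0.01 with TMM, so changes are given relative to the TMM scale.

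Other genes with the largest rises under the naming rule were Hist1h1b, a linker histone of dividing cells (log2 4.22, SE 0.71), the receptor Cd72 (4.18, SE 0.46), Lgals1 (3.90), Pclaf (3.89), Isg15 (3.88), Mki67 (3.80, edgeR adjusted p = 0.000243), Ifit3 (3.78) and, lower in that ranking, Ifitm3 (3.60). Some list members outside the rule rose more and are given below. The largest falls were in Upk1b (log2 -1.40, SE 0.35, adjusted p = 0.00683), Gpr165 (-1.39), Tnfrsf17 (-1.37), Tmem204 (-1.24), the cytokine receptor Il7r (-1.20), Trp53cor1 (-1.20), Mras (-1.16, SE 0.25), Sema4b (-1.09), Matk (-1.07) and Rac3 (-1.03). Of the genes always reported, Top2a (3.35), Cst7 (3.09), Lgals3 (2.76), Ccl4 (2.55) and Lpl (1.96) rose, and Cx3cr1 (-0.68) and Tmem119 (-0.43) fell. Lgals3 was -0.23 in hashed library 2 alone. Cd74 (0.64), Pf4 (1.00), Apoe (0.74), Mrc1 (-0.35) and Il1b (-0.52) did not pass (adjusted p = 0.0563 to 0.703). In sums of all cells Pf4 was -1.76 and Il1b 3.12, and both passed. On GRCm38 (GENCODE vM21), Spp1 lies on chromosome 5 from 104435118 to 104441050, Cxcl10 on chromosome 5 from 92346638 to 92348889, Fn1 on chromosome 1 from 71585520 to 71653200, P2ry12 on chromosome 3 from 59216272 to 59262871 and Upk1b on chromosome 16 from 38773184 to 38800328.

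**Figure D2:**
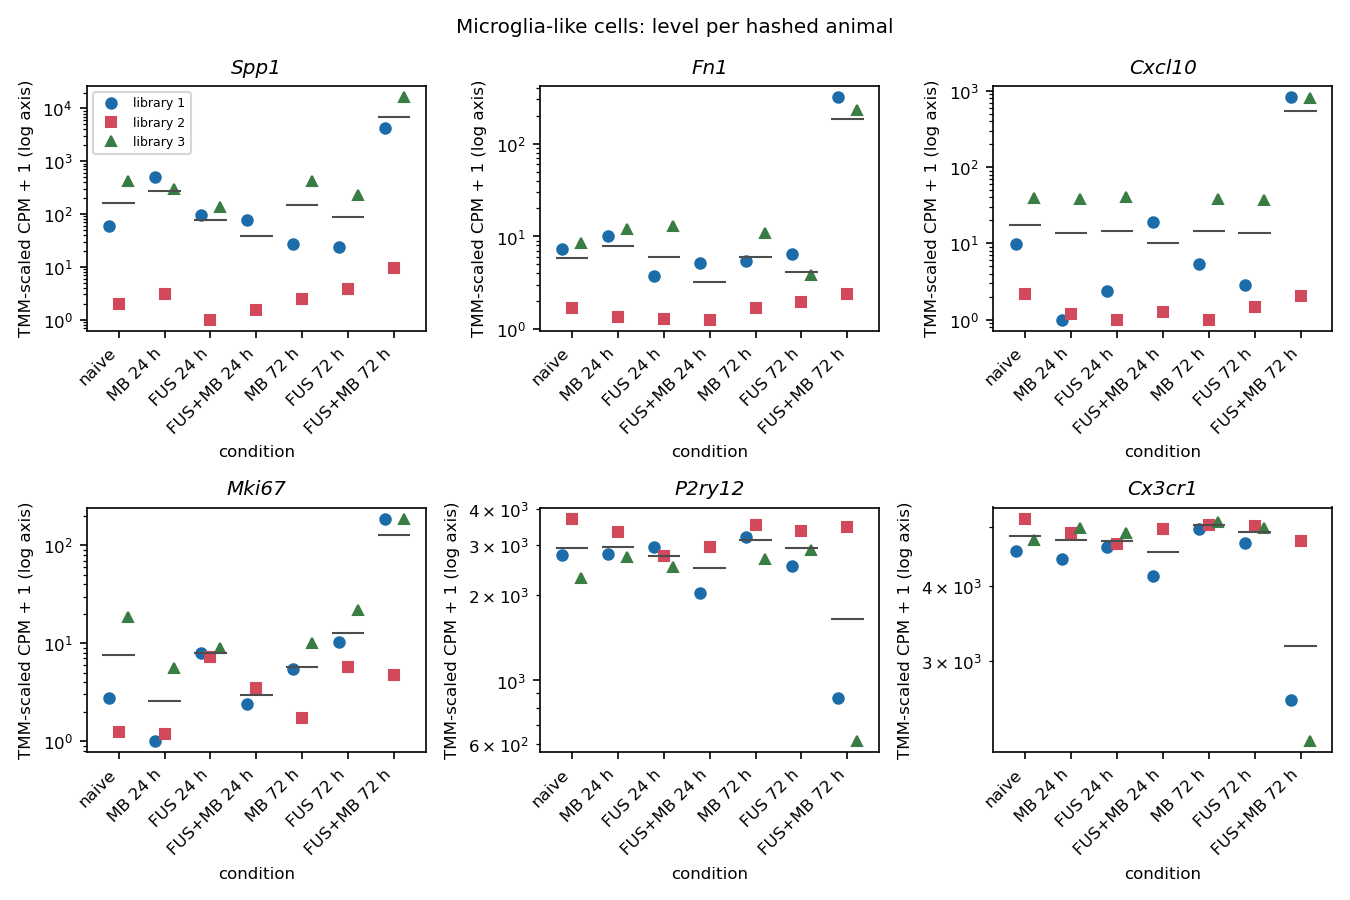
Levels of leading genes in microglia-like cells (TMM-scaled CPM + 1, log axis) by condition, with 1 point per hashed animal coloured by library and bars at condition means. Spp1 reaches 4300 and 16360 CPM in the FUS+MB animals of hashed libraries 1 and 3 at 72 h and 8.60 CPM in that of hashed library 2.

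Part of the activation genes rose at 72 h. Of 23 disease-associated microglia genes, 17 rose, 0 fell and the rest did not pass (19 higher and 1 lower adjusted over the list alone), with Fabp5 at 3.10, Axl at 2.22 and Igf1 at 2.21. Their median was 1.00 (camera adjusted p = 3.25e-10, and adjusted p = 0.138 with an estimated correlation). Trem2, the lipid-sensing receptor of these cells, was -0.22 and did not pass. All 20 interferon response genes rose (20 adjusted over the list alone), among them Rsad2 (4.79) and Zbp1 (4.15), with a median of 3.35 (camera adjusted p = 1.08e-19, and adjusted p = 0.138 with an estimated correlation). Of 19 inflammatory cytokine and NF-kB genes, 9 rose and 1 fell (the same counts adjusted over the list alone). The chemokines Ccl7 (4.70), Ccl5 (4.42) and Ccl12 (4.19) rose, and Nfkb1 fell (-0.38). The median was 0.25 (camera adjusted p = 0.00514, and adjusted p = 0.182 with an estimated correlation). Of 17 antigen presentation genes 7 rose (10 adjusted over the list alone), with the class I genes H2-Q7 at 2.27 and H2-K1 at 0.82. Their median was 0.36 (camera adjusted p = 0.00269, and adjusted p = 0.280 with an estimated correlation).

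Homeostatic genes fell. Of 20 homeostatic microglia genes, 0 rose and 15 fell (17 adjusted over the list alone), among them the fructose transporter gene Slc2a5 (-0.94), Crybb1 (-0.86), Siglech (-0.74) and the identity factor Sall1 (-0.72). The median was -0.69 (camera adjusted p = 5.58e-08, and adjusted p = 0.189 with an estimated correlation). Fcrls (0.15) and Olfml3 (0.14) did not pass. Microglia markers, a subset of that list, had 7 of 10 lower (8 adjusted over the list alone) and a median of -0.69 (camera adjusted p = 0.000202, and adjusted p = 0.182 with an estimated correlation).

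Division and metabolic genes rose as well. All 27 cell cycle genes rose (27 adjusted over the list alone), with a median of 3.06 (camera adjusted p = 3.83e-18). All 23 oxidative phosphorylation genes rose (23 adjusted over the list alone; median 1.00, camera adjusted p = 2.18e-19), as did 13 of 13 mitochondrially encoded genes (13 adjusted over the list alone; median 1.01, camera adjusted p = 3.19e-12). Of 15 glycolysis and hypoxia genes 12 rose, among them Mif (1.93), Pkm (1.83) and Gapdh (1.69), and 12 rose and 1 fell adjusted over the list alone (median 0.97, camera adjusted p = 2.02e-07). Ribosomal protein genes had 78 of 87 higher and 1 lower (79 and 1 adjusted over the list alone; median 0.87, camera adjusted p = 1.26e-33). Of 16 growth factor and tissue repair genes 11 rose (11 adjusted over the list alone), with the protease gene Mmp12 at 3.57 and a median of 0.70 (camera adjusted p = 1.92e-05). Each of these 6 lists had adjusted p = 0.138 with an estimated correlation.

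Handling of debris and lipid was mixed. Phagocytosis and lysosome genes had 13 of 27 higher, such as the scavenger receptor gene Msr1 (3.77) and Gusb (1.00), and 1 lower, the phagocytic receptor gene Mertk (-0.61). Adjusted over the list alone these were 16 and 2 (median 0.31, camera adjusted p = 0.000872, and adjusted p = 0.268 with an estimated correlation). Lipid handling genes had 7 of 17 higher, with Ch25h (4.86) and the lipid droplet gene Plin2 (2.54), and 1 lower, Mylip (-0.49), or 8 and 2 adjusted over the list alone (median 0.42, camera adjusted p = 0.000818, and adjusted p = 0.138 with an estimated correlation). The camera test did not call complement genes (3 of 9 higher, with C4b at 2.66; 3 higher and 1 lower adjusted over the list alone; median 0.27, adjusted p = 0.0818). Heme and iron genes were not called either (6 of 13 higher, with Hmox1 at 1.14, and 2 lower, with the iron exporter gene Slc40a1 at -0.73; the same counts adjusted over the list alone; median 0.44, adjusted p = 0.166). Immediate early and heat shock genes had 5 of 21 higher and 3 lower (the same counts adjusted over the list alone; median 0.15, adjusted p = 0.655). Alternative activation genes had Msr1 higher and Stat6 (-0.50) lower among 6 (the same counts adjusted over the list alone), with a median of -0.25, a mean of 0.44 and a camera direction of down (adjusted p = 0.725).

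Markers of other cells were measured in the same sums. Among border-associated macrophage markers 1 of 5 rose, Dab2 at 1.85 (median 0.80, camera adjusted p = 0.556), and among monocyte markers 2 of 7 rose, Ms4a4c at 1.73 and Plac8 at 1.46 (median 0.07, camera adjusted p = 0.561). Neutrophil markers (0 of 5, median -0.20, adjusted p = 0.325) and oligodendrocyte markers (0 of 3, median -0.35, adjusted p = 0.146) had no gene that passed in edgeR. Counts adjusted over the list alone were the same for these 4 lists. In hashed library 3 the sums came from the animal with 54.5% monocyte-like cells. List medians in hashed libraries 1, 2 and 3 were 3.39, 0.30 and 3.89 for interferon, 3.55, 0.24 and 3.11 for cell cycle, 0.98, 0.23 and 1.58 for disease-associated and -0.99, -0.02 and -1.13 for homeostatic genes.

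**Figure D3:**
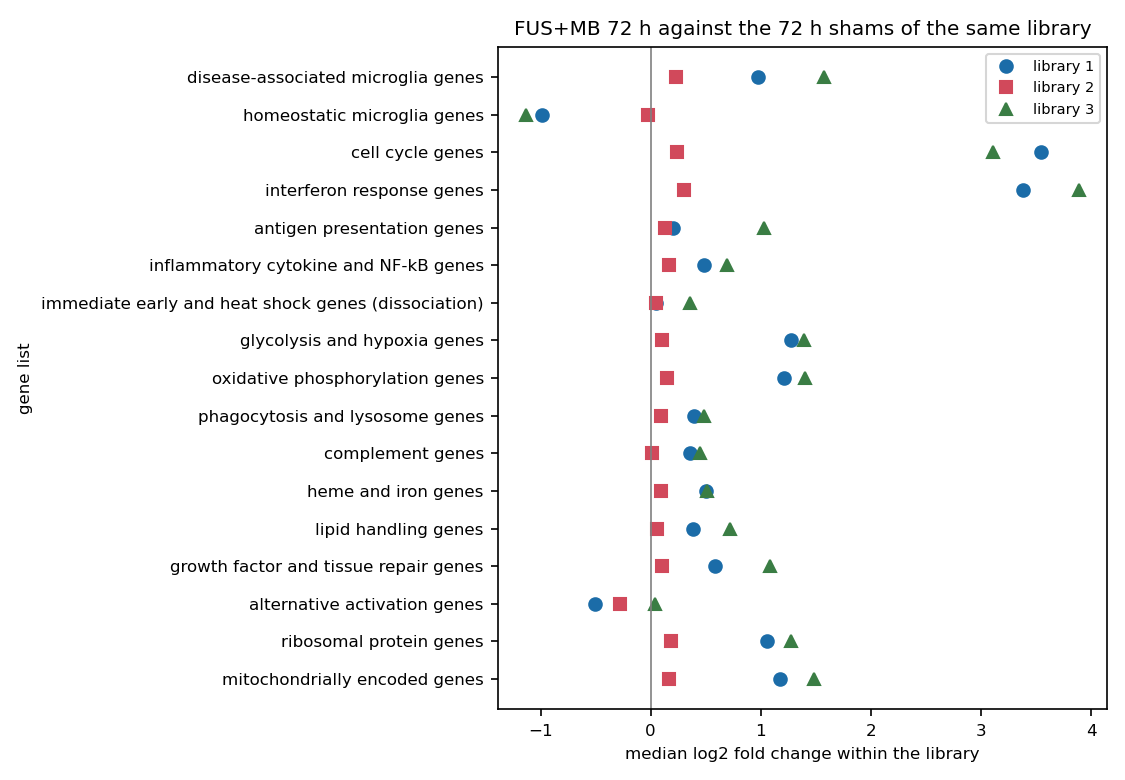
Median log2 change of each gene list in microglia-like cells at 72 h, FUS+MB animal against the shams of its hashed library, with 1 point per library. Interferon medians are 3.39, 0.30 and 3.89 in hashed libraries 1, 2 and 3.

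Cycling cells were counted directly. After thinning, 83 of 255 microglia-like cells (32.5%, 26.8 to 38.7) of the FUS+MB animal of hashed library 1 at 72 h carried mitotic transcripts, 4 of 564 (0.709%, 0.194 to 1.81) in hashed library 2 and 98 of 282 (34.8%, 29.2 to 40.6) in hashed library 3. Controls averaged 1.42% with a highest value of 4.09%. The difference of 21.3 points passed the two-sided exact permutation test (exact p = 0.0156, the smallest possible, adjusted p = 0.0312, higher in 3 of 3 libraries). In hashed library 2 the higher rank rests on few cells. Its 72 h FUS sham held 1 of 430, its 72 h MB sham 1 of 289 and its naive animal 1 of 833. Its 24 h FUS sham, outside this test, held 4 of 578 (0.692%). Without hashed library 1, 2 or 3 the difference was 16.3, 31.6 or 15.8 points and could not pass (smallest exact p 0.0625, adjusted p = 0.125). Thresholds of 1 and 3 UMIs gave 23.8 and 17.1 points (adjusted p = 0.0625 for both, exact permutation). At 24 h the difference was -0.230 points (exact p = 0.625). Neutrophil-like and border-associated macrophage-like cells, given as a background for free RNA, had 0 to 4.35% at median depths of 5098.5 to 9219 UMIs in the hashed libraries.

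**Figure D4:**
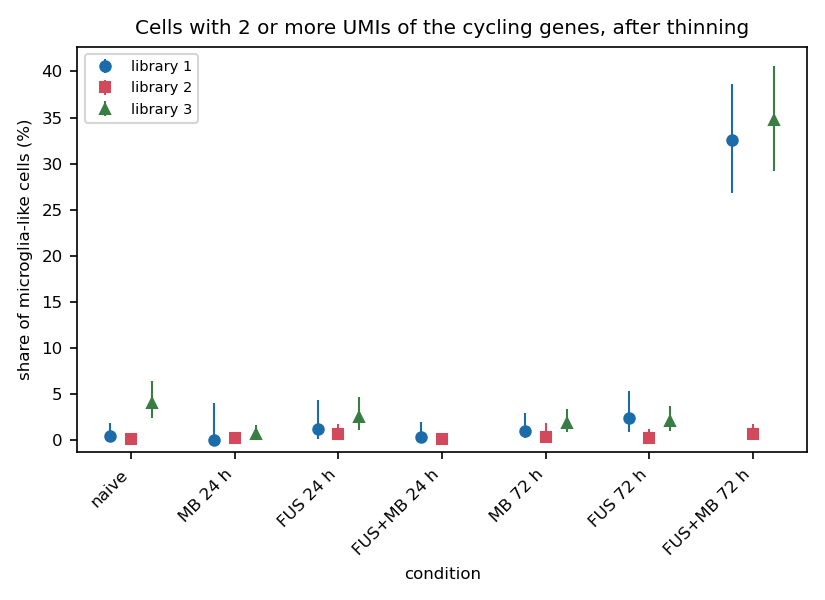
Share of microglia-like cells with mitotic transcripts (%, after thinning to 2000 UMIs) by condition, with 1 point per hashed animal and exact 95% intervals. The FUS+MB animals of hashed libraries 1 and 3 at 72 h stand at 32.5% and 34.8%, and that of hashed library 2 at 0.709%.

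The comparison of FUS+MB with shams at 24 h asks how microglia-like cells stand a day after FUS+MB, and no gene passed. The 2 FUS+MB animals were unlike in cluster 3. In hashed library 1 it held 17.3% of microglia-like cells, against 2.48% and 4.55% in the 24 h FUS and MB shams. In hashed library 2 it held 0.568%, against 0.692% and 0.276%. These cluster shares were not tested. Among the genes with the smallest p, Klf4, an immediate early transcription factor gene, was 18.6 ± 16.0 CPM in shams (SD, n = 6) and 84.2 and 11.6 CPM in the FUS+MB animals of hashed libraries 1 and 2 (log2 1.61, SE 0.41). Serpine1 (1.25, SE 0.33) and Per1 (1.05, SE 0.27) followed. On the lower side, Olfml3 was 1639 ± 164 CPM (SD, n = 6) against 1077 and 1293 CPM (-0.54, SE 0.13), Fcrls was 2059 ± 146 CPM (SD, n = 6) against 1525 and 1481 CPM (-0.48, SE 0.12), and Hist1h2bc changed by -0.997 (SE 0.28). Ccl4, a chemokine gene, was 31.2 ± 27.1 CPM (SD, n = 6) against 121 and 129 CPM (2.45, SE 0.72). In edgeR 0 of 10546 genes passed (adjusted p = 1 for those named), 255 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Without hashed library 3 no gene passed in edgeR. Without hashed library 1 or 2 only 1 FUS+MB animal remains, so no count is given here. Fitting only these conditions called 19 genes.

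Among the lists at 24 h, camera called 5, none of which held with an estimated correlation. Inflammatory cytokine and NF-kB genes had a median of 0.39 (adjusted p = 7.88e-07, and adjusted p = 0.0679 with an estimated correlation), with 0 of 19 genes past the test over all genes and 3 adjusted over the list alone. Immediate early and heat shock genes had 0 of 21 and 2 higher adjusted over the list alone (median 0.18, adjusted p = 0.000351, and adjusted p = 0.0972 with an estimated correlation). Interferon genes had 0 of 20 by either count (median 0.19, adjusted p = 0.0422, and adjusted p = 0.994 with an estimated correlation), and their median was -0.39 without the library block. Homeostatic genes had 0 of 20 and 2 lower adjusted over the list alone (median -0.23, adjusted p = 1.73e-08, and adjusted p = 0.411 with an estimated correlation), and microglia markers 0 of 10 and 2 lower (median -0.22, adjusted p = 8.93e-06, and adjusted p = 0.311 with an estimated correlation). Medians in hashed libraries 1 and 2 alone were -0.36 and -0.04 for homeostatic, -0.33 and -0.03 for microglia marker, 0.45 and 0.01 for interferon, 0.32 and 0.14 for immediate early and 0.41 and 0.27 for cytokine genes. Leaving out hashed library 3 gave 4 called lists, and interferon genes were then not called (camera adjusted p = 0.0974).

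The other lists at 24 h were not called (camera adjusted p = 0.257 to 0.981), with no gene past the test over all genes. Medians were 0.08 for disease-associated (camera direction down), 0.07 for antigen presentation, 0.05 for ribosomal, 0.02 for lipid handling, 0.03 for growth factor (camera direction down), -0.01 for glycolysis, -0.01 for complement (mean 0.23, direction up), -0.03 for phagocytosis (mean 0.06), -0.03 for mitochondrially encoded (mean 0.01, direction up), -0.05 for oxidative phosphorylation, -0.05 for heme and iron, -0.08 for alternative activation and -0.13 for cell cycle genes (direction up). They were 0.15 for border-associated macrophage (mean -0.28), -0.67 for monocyte, -0.19 for neutrophil and 0.12 for oligodendrocyte markers. Adjusted over the list alone, 1 alternative activation gene was lower and no gene of these other lists passed. Genes always reported were Lgals3 0.87, Lpl 0.83, Il1b 0.71, Ifitm3 0.56, Cd74 0.55, Pf4 0.28, Apoe 0.27, Mki67 0.18, Mrc1 0.15, Cst7 -0.01, Cx3cr1 -0.10, Tmem119 -0.14, P2ry12 -0.37, Top2a -0.39 and Spp1 -0.72 on the log2 scale (all adjusted p = 1).

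The difference between the times was tested by the interaction, in which 1 gene passed in edgeR. Fn1 had a FUS+MB effect larger by 6.38 on the log2 scale (SE 0.86, adjusted p = 0.00557) at 72 h than at 24 h, 5.997 in hashed library 1 and 0.459 in hashed library 2. DESeq2 called 385 genes and limma-voom 0, and 1970 edgeR genes had an unadjusted p under 0.05. The count was 1 without hashed library 3 and 0 without the library block. The gene called without hashed library 3 was not Fn1, which did not pass there. Without hashed library 1 or 2 only 1 FUS+MB animal at 24 h remains, so no count is given here. Camera called 13 lists, led by cell cycle (median 3.29), interferon (2.94) and mitochondrially encoded genes (1.04), and none held with an estimated correlation (adjusted p = 0.162 to 0.502).

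Against naive animals, FUS+MB at 72 h changed 1880 genes in edgeR, 1469 higher and 411 lower (limma-voom 1358). With library size scaling alone 2458 genes passed, 899 higher and 1559 lower, so the balance of directions depends on the scaling. The FUS+MB animals are those of the comparison with shams, so the comparisons are not independent. Largest rises were in Spp1 (5.37, SE 0.76), Fn1 (4.96), Cd72 (4.43), Mki67 (4.19), Pclaf (3.95), Ube2c (3.89), the inhibitory receptor gene Lilrb4a (3.84), Birc5 (3.84), Ifi27l2a (3.78) and Ifitm3 (3.74). Largest falls were in Upk1b (-1.57, SE 0.37), Il7r (-1.53), Gpr165 (-1.44), Mras (-1.35), Fkbp5 (-1.34), Tnfrsf17 (-1.31), the glutamate transporter gene Slc1a3 (-1.21), Rcan1 (-1.18), Trp53cor1 (-1.18) and Tmem204 (-1.17). Camera called 14 lists, among them disease-associated (15 of 23 higher; 17 adjusted over the list alone), interferon (19 of 20; 20 adjusted over the list alone), cell cycle (27 of 27; 27 adjusted over the list alone) and homeostatic genes (11 of 20 lower; 16 adjusted over the list alone), and none held with an estimated correlation (adjusted p = 0.132 for the first 3 and 0.179 for homeostatic genes). The count was 1, 4371 and 8 without hashed libraries 1, 2 and 3, 1037 without the block, 30 with only these conditions and 56 without the cycling-led clusters.

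FUS+MB at 24 h against naive had 0 genes past the edgeR test (328 with an unadjusted p under 0.05; DESeq2 1, limma-voom 0). Smallest p were those of Nfkbia, an NF-kB inhibitor gene (0.89), Igfbp6 (4.24, from near 0 CPM) and Serpine1 (1.43), and of Cryba4 (-0.59), Fam72a (-1.21) and Fcrls (-0.57), with adjusted p = 0.989 to 1.00. Camera called cytokine (median 0.51; 2 higher adjusted over the list alone), ribosomal (0.14; 0), homeostatic (-0.23; 2 lower) and microglia marker lists (-0.23; 2 lower), with no member past the test over all genes and adjusted p = 0.104, 0.981, 0.495 and 0.495 with an estimated correlation. With only these conditions the count was 147, and without hashed library 3 it was 0. Without hashed library 1 or 2 only 1 FUS+MB animal remains, so no count is given here.

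From 24 h to 72 h after FUS+MB, 599 genes passed in edgeR, 521 higher and 78 lower. With library size scaling alone 409 passed, 139 higher and 270 lower, so the balance of directions depends on the scaling. No sham is subtracted in this contrast, so changes with time that shams share are not separated from it. Rises were led by Fn1 (5.65, SE 0.66), Spp1 (5.60), Top2a (4.87), Hist1h1b (4.80), Cxcl10 (4.75), Birc5 (4.61), Mki67 (4.31), Pclaf (4.15), Ifi27l2a (3.75) and Fabp5 (3.55). Ddit4, a stress- and glucocorticoid-induced gene, fell by 3.36 on the log2 scale (SE 0.64), from 349 and 171 CPM to 19.9, 35.1 and 40.6 CPM. Other falls were in the glucocorticoid-induced Tsc22d3 (-1.95) and Fkbp5 (-1.48), and in Adrb1 (-1.57), Rcan1 (-1.33), Tagap (-1.32), Rgs1 (-1.24), Nfkbia (-1.20), Mex3b (-1.13) and Zkscan14 (-1.11). Camera called 14 lists, led by ribosomal (70 of 87 higher; 78 adjusted over the list alone), oxidative phosphorylation (19 of 23; 23 adjusted over the list alone), cell cycle (21 of 27; 27 adjusted over the list alone) and interferon genes (16 of 20; 20 adjusted over the list alone), none of which held with an estimated correlation (adjusted p = 0.126 for these 4). Homeostatic genes had a median of -0.33 and a camera direction of down, while the 2 members that passed rose. Limma-voom called 6 genes (2 higher and 4 lower), the fit without the block 0, all cells 0, only these conditions 101 and no cycling-led clusters 10. Leaving out hashed library 3 gave 4.

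Comparing shams with naive animals asks what either component of the treatment does when given alone. In edgeR 0 genes passed for 24 h shams (130 with an unadjusted p under 0.05; DESeq2 0, limma-voom 0) and 0 for 72 h shams (179; DESeq2 0, limma-voom 0). Per3 (1.71, SE 0.42), Nr1d1 (1.84, SE 0.47) and Dbp (1.85, SE 0.50) had the smallest p among higher genes at 24 h, and Xlr4b (-1.15), Xlr4a (-2.05) and Hist1h2ac (-1.24) among lower ones (adjusted p = 1.00). At 72 h these were Ercc6l2 (0.72), Cpq (0.65) and Zbtb24 (0.56), and Per1 (-1.18), Gdf15 (-3.87) and Rgs1 (-0.79). Camera called ribosomal genes at 24 h (median 0.08, adjusted p = 0.00177, and adjusted p = 0.988 with an estimated correlation) and at 72 h (median 0.16, adjusted p = 2.65e-09, and adjusted p = 0.984 with an estimated correlation), with 0 of 87 genes past the test over all genes or adjusted over the list alone. Without hashed library 2 the counts were 3 and 12.

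FUS shams against MB shams, with both times averaged, gave 0 genes in edgeR (204 with an unadjusted p under 0.05; DESeq2 0, limma-voom 0; 3 without hashed library 2). Smallest p were those of Sertad3 (0.53), Nup50 (0.51) and Cep162 (0.52), and of Per1 (-0.87), Asah2 (-0.69) and Ccdc80 (-1.66). Cell cycle genes had a median of 0.74 (camera adjusted p = 5.54e-19, and adjusted p = 0.376 with an estimated correlation), immediate early genes 0.12 (adjusted p = 0.0128, and adjusted p = 0.376 with an estimated correlation) and ribosomal genes 0.12 (adjusted p = 3.80e-08, and adjusted p = 0.728 with an estimated correlation), with no member past the test over all genes or adjusted over the list alone.

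The pooled libraries compare FUS+MB with MB at 24 h without replicates or a p. Immediate early genes were higher throughout after FUS+MB, with Fos at 1336 against 1.25 CPM (log2 ratio 10.06, 9.38 to 10.84) and Egr1 at 1509 against 9.77 CPM (7.27). Spp1 was 617 against 2.72 CPM (7.83), the aggrecan-degrading protease gene Adamts1 410 against 2.06 CPM (7.64), Tnf 518 against 3.45 CPM (7.23) and Lilr4b 7.05 on the log2 scale. Cxcl2, a neutrophil chemokine gene, had 111 CPM against 0 UMIs, a log2 ratio of 8.98 against the floor of 3 UMIs in that library and of at least 8.68 by the exact limit. Mmp12 (2 UMIs in MB; 7.70 to 12.60), Il1rn (2 UMIs; 6.10 to 11.01) and Fosb (1 UMI; 6.03 to 13.82) completed the 10 largest. Lower genes were Ano7 (-4.35), the clock-linked Hlf (-3.66) and Dbp (-2.98), Klrd1 (-3.42), Sept1 (-3.30), Trim5 (-3.17), Izumo4 (-3.13), Sema4b (-3.01), Lrrc39 (-2.93) and Fry (-2.86). P2ry12 was 472 against 2490 CPM (-2.40), Cx3cr1 2360 against 6488 CPM (-1.46), Tmem119 833 against 1922 CPM (-1.21) and Ccl4 7619 against 154 CPM (5.63). Lgals3 (5.996), Lpl (4.32), Il1b (3.64), Ifitm3 (2.71), Cst7 (2.63), Cd74 (1.90), Pf4 (1.65), Top2a (1.19), Mrc1 (0.44), Apoe (0.28) and Mki67 (-0.87, 24 UMIs in all) were the others always reported. Of the microglia-like cells, 76.0% of the FUS+MB pool lay in cluster 2 and 22.1% in cluster 1, and 97.1% of the MB pool in cluster 12, so these ratios compare cells of almost separate clusters. Clusters were made without correction for library, and 3106 of 3148 cells of cluster 12 came from the MB pool. Hashed MB animals at 24 h had at most 0.857% of microglia-like cells there. Cluster 2 held 3.17% and 0.284% in the FUS+MB animals at 24 h of hashed libraries 1 and 2. The separation thus follows library, and any part set by treatment cannot be told apart from it. Fos lies on chromosome 12 from 85473890 to 85477273 and Ccl4 on chromosome 11 from 83662584 to 83664683 (GRCm38).

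Of 8716 genes, 306 differed at least 4-fold, 160 higher and 146 lower, around a median of -0.29. With TMM scaling these were 235 and 66 around a median of 0.06. List medians, with members higher, were 3.97 for immediate early (23 of 23), 3.67 for cytokine (20 of 22), 1.45 for glycolysis (14 of 15), 1.44 for cell cycle (12 of 12), 1.25 for interferon (9 of 12) and 1.09 for growth factor genes (10 of 13). These 6 lists and ribosomal genes (0.64, 77 of 86) stood at percentile 100 of the matched random lists. Disease-associated genes (0.67, 14 of 20, percentile 99.8) and oxidative phosphorylation (0.52, 23 of 23, 98.9) followed. Lipid handling genes were at 0.27 (10 of 17, 97.2), and at -0.18 (5 of 11, 29.1) among genes with at least 1000 UMIs, where disease-associated genes stood at percentile 92.7. Homeostatic genes (-1.33, 1 of 20) and microglia markers (-1.51, 1 of 10) stood at percentile 0. Medians near 0 were 0.21 for mitochondrially encoded (10 of 13, 53.8), 0.14 for alternative activation (2 of 4, 84.4), 0.13 for heme and iron (8 of 13, 88.9), 0.00 for phagocytosis (13 of 26, 22.6), -0.09 for complement (3 of 7, 22.9; 0.26 with TMM) and -0.13 for antigen presentation genes (6 of 14, 41.7; 0.21 with TMM). Border-associated macrophage markers were 1.65 (2 of 3, 99.7), and -1.61 over all cells, and astrocyte markers -0.80 (0 of 3, 17.3).

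**Figure D5:**
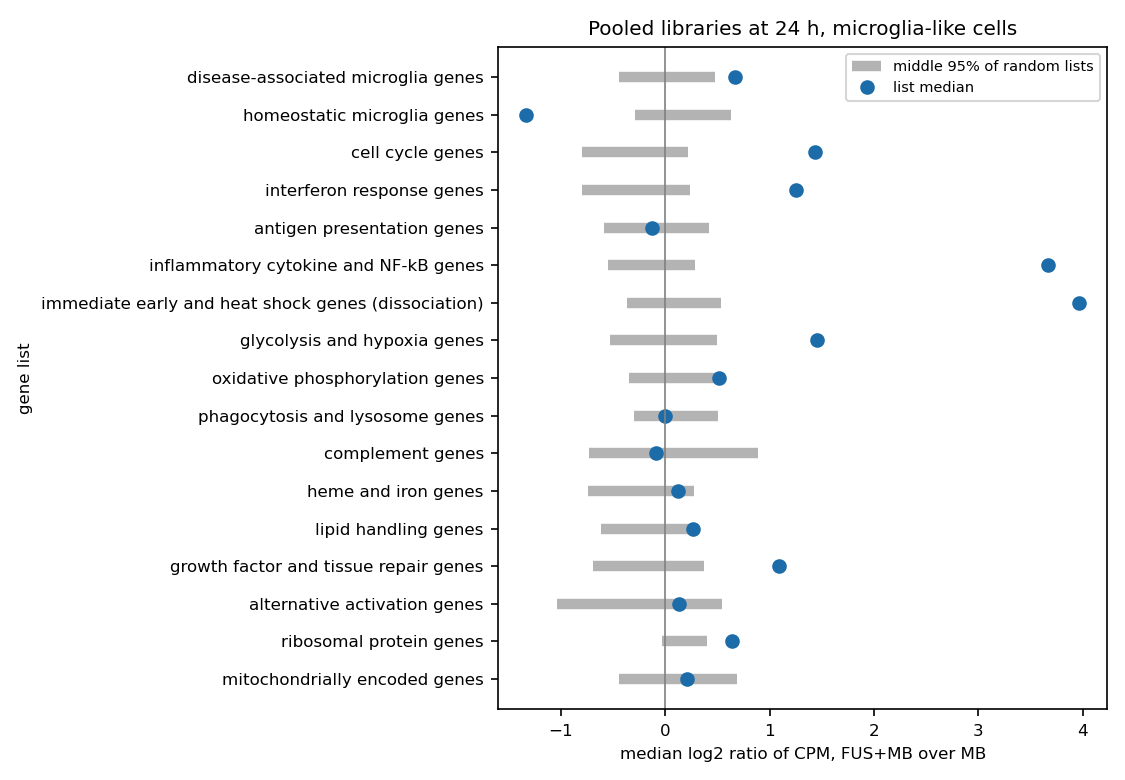
Median log2 ratio of each gene list between the pooled FUS+MB and MB libraries at 24 h (points), with the central 95% of 10000 matched random lists (grey bars). Immediate early genes stand at 3.97 and homeostatic genes at -1.33.

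Cell classes also differed between the pools. Monocyte-like cells were 66 of 2184 (3.02%, 2.34 to 3.83) after FUS+MB and 1 of 3310 (0.0302%, 0.000765 to 0.168) after MB. Dendritic-like cells were 1.51% and 0.363%, border-associated macrophage-like cells 0.733% and 2.21%, and microglia-like cells 92.4% and 96.6%. Cycling cells were 0.545% and 0.375%. Because no gene passed at 24 h in hashed animals, the planned count of shared directions had no gene to count. Among 238 genes with an unadjusted p under 0.05 there, a choice made after seeing the data, 169 (71.0%, 64.8 to 76.7) had the same sign in the pools, against 59.1% of all 9973 genes. With TMM scaling these shares were 77.3% and 59.9%. The interval treats genes as independent, which they are not, and does not measure a spread over animals.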

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

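The tests of hashtag exchange and depth in hashed library 2, of handling in the pools and of the splits were chosen only after the results were seen.

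A difference between times drew attention to Fn1, whose FUS+MB effect in edgeR was larger by 6.38 on the log2 scale at 72 h than at 24 h (adjusted p = 0.00557). The same test of the difference called 13 lists in camera. Their medians were 3.29 for cell cycle genes (27 members passing adjusted over the list alone), 2.94 for interferon (19), 1.04 for mitochondrially encoded (13), 1.01 for oxidative phosphorylation (22), 0.99 for glycolysis and hypoxia (11) and 0.98 for disease-associated genes (12). They were 0.81 for ribosomal protein (77), 0.62 for growth factor and tissue repair (5), 0.47 for lipid handling (3), 0.42 for antigen presentation (1), 0.40 for heme and iron (4) and 0.40 for phagocytosis and lysosome genes (0). Homeostatic genes had a median of -0.39 with a camera direction of down, while the 2 members that passed adjusted over the list alone were higher. Camera adjusted p ran from 1.00e-28 for ribosomal to 0.0332 for heme and iron genes, and with an estimated correlation no list was called (adjusted p = 0.162 to 0.502).

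The FUS+MB animal of hashed library 2 at 72 h showed little of the response of the other FUS+MB animals of that time. An exchange of hashtags with another animal of that library is argued against, since the highest interferon median among its 7 animals was 0.33, against 3.70 and 3.64 in the FUS+MB animals of hashed libraries 1 and 3. Low depth is also argued against, since its microglia-like sum held 2884818 UMIs, against 2085882 and 2305310. A single wrong label or an exchange with an animal outside the library stays open, as does a treatment that did not open the barrier in this animal, and neither was tested.

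Immediate early and cytokine genes stood far higher, and homeostatic genes lower, in the pooled FUS+MB library than in the pooled MB library. A few genes taking most of the counts are argued against as the whole cause of the homeostatic difference. With the immediate early and cytokine lists out of the totals, of which they held 4.71% in the FUS+MB pool and 0.492% in the MB pool, the homeostatic median was -1.27 instead of -1.33. Handling or dissociation that differed between the pools cannot be told apart from treatment, because each treatment was 1 library. In hashed animals the immediate early median at 24 h was 0.18. Those animals were combined only after staining, so they shared a channel but not the dissociation before it. The value therefore does not decide about handling.

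In microglia-like cells at 72 h, 20 of 20 interferon, 27 of 27 cell cycle and 17 of 23 disease-associated genes rose in edgeR, and no list was called with an estimated correlation (adjusted p = 0.138 for these 3). In hashed libraries 1 and 3 this compares cells of almost separate clusters, with 55.3% and 44.7% of the FUS+MB animals' microglia-like cells in cluster 3 and 32.2% and 45.4% in cluster 11. RNA of monocyte-like or dendritic-like cells that carries their fixed markers is argued against as the source of most of the rise. By the marker that allowed most of it, such RNA accounted for a median of 0.152% of the rise of the called genes in hashed library 1. In hashed library 3 this was 0.0649%. For 17 and 13 genes at least 50% of the rise could come from such RNA, and these stay open. The same markers had kept such clusters out of the microglia-like class. Cells from blood that lack these markers are therefore not covered by this test and stay open. A biological response to FUS+MB is a hypothesis that rests on the animals of hashed libraries 1 and 3.

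For FUS+MB against shams at 72 h, 3 of 27 splits within libraries called as many genes (2809 in the real split, 2942 as the highest other), so chance cannot be excluded. Both other splits exchanged only the FUS+MB animal of hashed library 2 with a sham, and every remaining split within libraries called 0. Of 57 further splits across libraries, 2 called as many. The 4 of these with the most calls (2302 to 3408) each held the FUS+MB animals of hashed libraries 1 and 3. Against naive, 1 of 4 splits called as many genes as the real split (1880, highest other 1420), which is the real split itself and too few splits to judge. The real counts were 0 for 24 h shams against naive (27 of 27 splits called as many, highest other 0), for 72 h shams against naive (27 of 27, highest other 1) and for FUS against MB shams (32 of 32, highest other 0). Any split reaches a count of 0, so these splits decide nothing.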

How the results depend on the processing

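Added after seeing the data were limma-voom, library size scaling alone, the doublet score setting, the removal of cycling-led clusters, edgeR on class counts and directions at an unadjusted p. Of the values answering a comparison, 171 stayed, 62 moved, 5 weakened and 1 reversed; of those for single genes, lists and shares, 1879 stayed, 77 moved, 23 became stronger, 388 weaker and 40 reversed. The cause was not tested, unless fewer animals or cells show it. In comparisons that use FUS+MB at 24 h, leaving out hashed library 1 or 2 leaves only 1 such animal. The upper ends of their ranges below come from fits without hashed library 2. These counts rest on that 1 animal and are not evidence of a response at 24 h. Genes called with each hashed library left out ran from 0 to 117 for FUS+MB against shams at 24 h and from 7 to 4990 at 72 h. Against naive they ran from 0 to 58 at 24 h and from 1 to 4371 at 72 h. They ran from 0 to 2477 for 72 h against 24 h, from 0 to 1756 for the interaction, from 0 to 3 and from 0 to 12 for 24 h and 72 h shams against naive, and from 0 to 3 for FUS against MB shams. Without the library block the counts were 1799 and 1037 for FUS+MB at 72 h against shams and naive, and 0 for 72 h against 24 h and for the interaction, and no other count moved by as much. With no filter on low counts they were 9 and 6 for FUS+MB at 24 h against shams and naive, 1073 for 72 h against 24 h, 2 for 24 h shams and 716 for the interaction. DESeq2 gave 2 and 1 for FUS+MB at 24 h against shams and naive and 385 for the interaction. Limma-voom gave 6 for 72 h against 24 h and 0 for the interaction. With library size scaling alone 34.6%, 36.6% and 34.0% of the genes called were higher for FUS+MB at 72 h against shams, naive and 24 h. With TMM these were 69.6%, 78.1% and 87.0%. All cells gave 2 and 2 for FUS+MB at 24 h against shams and naive, 0 for 72 h against 24 h and 0 for the interaction. Only the conditions of a contrast gave 19 and 147 at 24 h and 1034 and 30 at 72 h against shams and naive, 101 for 72 h against 24 h and 6 for 24 h shams. Without cycling-led clusters the counts were 10 and 56 at 72 h against shams and naive, 10 for 72 h against 24 h and 0 for the interaction, which was 2 with stricter cell filters and 0 with the own hashtag assignment. With an estimated correlation, 0 lists were called in each of the 9 comparisons. EdgeR on class counts called 2 classes at each time. The cycling difference at 72 h was 23.8 and 17.1 points with 1 and 3 UMIs, and 15.8 to 31.6 with a library left out; at 24 h it was 0.0417 with 3 UMIs. Pooled genes at least 4-fold apart were 579 with 50 UMIs and 108 with 1000 UMIs. Shared directions were 2 with all cells and 169 at an unadjusted p.

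Values that turned at 24 h against shams had not passed for any single gene. Without the library block interferon genes were -0.39, Cd74 -0.17, Ifitm3 -0.66 and Mki67 -0.69. With all cells Apoe was -0.12, Pf4 -2.51, Mrc1 -1.45 and Mki67 -0.23. With each hashed library left out, ranges were -0.87 to 1.73 for Lgals3, -1.02 to 1.27 for Il1b, -1.47 to 0.35 for Spp1, -0.0544 to 0.57 for Mrc1, -0.49 to 0.30 for Top2a, -1.53 to 1.52 for Mki67 and -0.19 to 0.20 for Cst7. With the own hashtag assignment Spp1 was 0.74 and Cst7 0.14. Limma-voom gave 0.20 for Top2a and 0.0259 for Cst7, DESeq2 0.12 for Top2a, library size alone 0.0196 and the doublet score setting 0.0472 for Cst7, cycling-led clusters left out -0.0611 for Mrc1, and only these conditions -0.0432 for Mki67. At 72 h all cells gave -1.76 for Pf4 and 3.12 for Il1b, and in the pools -1.61 for border-associated macrophage markers, -0.36 for Apoe and -1.64 for Pf4. Share differences at 24 h turned to -0.228 (Leiden resolution 2) and -0.0169 (stricter filters) for microglia-like cells, and with a library left out ran from -0.565 to 0.770 for microglia-like, 0 to 2.31 for monocyte-like, -0.0394 to 1.72 for dendritic-like and -0.103 to 0.990 for lymphoid-like cells. At resolution 0.5 the cluster that the naming rule called lymphoid-like was led by the neutrophil genes S100a8 and S100a9, so its -0.624 at 24 h and -0.0831 at 72 h do not measure lymphoid-like cells. At 72 h with a library left out lymphoid-like cells ran from -0.118 to 0.322, and border-associated macrophage-like cells from -0.643 to 0.0546.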

Other observations

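Per3, Nr1d1 and Dbp were the higher genes with the smallest p between 24 h shams and naive animals. In microglia-like cells, Per3, a period gene of the circadian clock, was 53.0 ± 10.6 CPM in 24 h shams (SD, n = 6) and 15.9 ± 4.62 CPM in naive animals (SD, n = 3), with log2 changes of 2.13, 1.51 and 1.45 in hashed libraries 1, 2 and 3. Dbp, a clock output gene, was 34.0 ± 10.7 against 9.35 ± 1.25 CPM (SD, n = 6 and 3), and Nr1d1, a clock repressor gene, 9.12 ± 3.97 against 2.57 ± 1.51 CPM (SD, n = 6 and 3). None passed in edgeR (adjusted p = 1.00), and the time of day at which animals were killed was not known here. At 72 h Per3 changed by 0.52 and Dbp by 0.43. In the pools, Dbp was lower after FUS+MB (-2.98).

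Other cells were few. Choroid plexus-like or ependymal-like cells, led by Ttr and Enpp2, were 26 of 2184 (1.19%, 0.779 to 1.74) in the pooled FUS+MB library and 2 of 3310 (0.0604%, 0.00732 to 0.218) in the pooled MB library. Neutrophil-like cells were 0.412% and 0.151%, and lymphoid-like cells 0.321% and 0.0906%.

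Levels of induced genes in control animals are given by library. Cxcl10 was 36.2 to 39.6 CPM in all 5 control animals of hashed library 3, 0 to 8.74 CPM in those of hashed library 1 and 0 to 1.17 CPM in those of hashed library 2. Spp1 was 134 to 418 CPM in the controls of hashed library 3. No empty droplets were analysed here, so free RNA of the channel was not separated from expression in these values. Median UMIs per cell of the 72 h FUS+MB animals were 7987, 4996 and 9709 in hashed libraries 1, 2 and 3, against 3791 to 4990 in the other hashed animals.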
